A study of Triticum aestivum with 8 samples.

How the data were processed

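Total RNA from leaf and crown of a synthetic hexaploid wheat line was labelled with Cy3 and hybridised to 8 one-colour Agilent oligonucleotide arrays, 2 for each of 4 groups: leaf and crown at 24 °C, leaf after 12 weeks and crown after 6 weeks at 4 °C. The groups were taken from the sample labels. Per the file headers, the scanner files hold intensity values made by Agilent Feature Extraction in versions 9.5.3.1 for leaf at 24 °C, 10.5.1.1 for both groups at 4 °C and 10.7.3.1 for crown at 24 °C. The submitters' processing notes name version 9.5. Per the file headers, the other columns used hold flags of kind other, 0 or 1 per spot, and the class of the spot. The authors also deposited a normalized table of intensity, in which each column was found to be the processed signal of an array multiplied by a single factor between 0.993 and 1.89. How the factor was set is not stated.

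The processed signal, background-subtracted within the array by the scanner software, was taken to log2 and reduced by the array's 75th percentile over the 37826 non-control probes; 1417 control spots were set aside. A group-means model over all 8 arrays was fitted with limma 3.58.1 in R 4.3.3, with 4 residual degrees of freedom and 1.55 prior degrees of freedom. Contrasts were the cold response in leaf and in crown, the difference of these, and crown against leaf at 24 °C. In each contrast the probes well above background on both arrays of at least 1 of the groups compared were tested, and p-values were adjusted by the Benjamini-Hochberg method over them. A probe was called at an adjusted p below 0.05 with a change of at least 2-fold. With 2 arrays against 2, an exact permutation test cannot go below a two-sided p of 0.333, so no such test was used. For Wcor15, at background in both controls, the fold was taken against the mean lowest signal well above background on the control arrays. The fit and the calls were tested on simulated data in which 200 probes were changed. Of the changes of 2.5-fold, 82.1% were called in leaf, 91.0% in crown and 61.2% in the difference of responses. Per comparison, 4 to 6 unchanged probes were called. The simulated values had normal noise of the fitted spread, without scaling, a detection limit or a scan day effect. Far fewer probes changed in them than were called in the data, so these rates are not the error rates of the calls made here.

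The main choices, the alternatives and the 36 gene lists were fixed before the data were examined. The lists read gene annotation, which the files used here do not hold, so that 2 lists matched any probe, with at most 2 probes each, under the minimum of 5 for a set test, and no set test was run on them. The list of cold and dehydration genes held cor47 and Wcor15, and the list of DREB factors held DREB2A and DREB2B. The rule for named genes took the called probes with the largest rises and falls among those well above background on all arrays compared and annotated with a protein. Without annotation that condition was dropped, and 1 rise and 1 fall per cold response were named, a number set after the values were seen. The gene-symbol probes were named because they carry a gene name in the file.

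The alternatives planned were quantile normalization, scaling to the median, the authors' table, no filter on dim probes, a filter on all arrays, a fit of the groups compared alone, replicate number as a block, no fold threshold, limma treat against 1.5-fold, an intensity trend with a robust prior, 1 probe per contig or clone, outlier spots set to missing, and leaving out each array in turn. Normexp background correction with an offset of 50 was planned on the mean spot signal, which the files do not hold, and was run on the median spot signal instead. That change, slide as a random block, a filter on all arrays compared, a common floor, scaling to the E1A spike-in controls, cyclic loess, the tissue comparison at 4 °C, the probe-name families and the study of probes that fell strongly in both tissues were chosen after the data were seen. Figures were drawn with matplotlib 3.10.9. Control spots other than the E1A spike-ins and the eQC-40 control were not used here.

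Each group was scanned on a single day of its own, 4 days in all, on 5 slides and 2 scanners, with leaf at 24 °C on a scanner of its own. Scan day could not be fitted as a term, since it and the group cannot be told apart. Slide was fitted as a random block, which does not separate it from the group, as no slide holds arrays of more than 1 group. The estimated correlation within slides was -0.709. Only leaf at 24 °C had its arrays on 2 slides, so this fit is no check on slide effects.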

Results

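The study measured transcript levels in a synthetic hexaploid wheat line, that is, a bread wheat rebuilt by crossing its ancestral species, before and after long growth in the cold. RNA from 2 tissues was hybridised to oligonucleotide arrays: the leaf, and the crown, the base of the shoot that holds the shoot apical meristem. The control samples came from plants grown for 3 weeks at 24 °C, and the cold samples from plants that then spent 12 weeks (leaf) or 6 weeks (crown) at 4 °C. Each of the 4 groups had 2 arrays, so n = 2 throughout, and this number limits the precision of every value. The titles, source names and tissue entries call the crown controls crown, whereas their free-text descriptions speak of leaves. On the arrays they correlated across probes with the crown samples at 4 °C at r = 0.915 to 0.919 and with the leaf controls at 0.774 to 0.776.

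Each array carried 37826 probes of 1 spot each. Between 72.1% and 73.1% of them lay well above background on the leaf arrays at 24 °C, 77.3% to 79.3% on those at 4 °C, 75.1% to 75.3% on the crown arrays at 24 °C and 84.9% to 85.6% on those at 4 °C. The lowest signal counted as well above background, on the log2 scale relative to each array's 75th percentile, was -6.35 and -6.04 on the leaf arrays at 24 °C and -7.89 and -8.19 on those at 4 °C. On the crown arrays it was -6.09 and -6.08 at 24 °C and -8.47 and -8.38 at 4 °C. No probe was saturated on any array. The 2 arrays of a group differed by a median of 0.0674 to 0.0894 on the log2 scale over the probes well above background on both. Nearly all probes are named by contig or clone, and the files do not pair these names with genes: 6 probes carry a gene name, and none of these or of the 41 probes named by a sequence accession was found in the reference gene table. The text therefore names those 6 genes, and otherwise the probe with the largest rise and the probe with the largest fall in each tissue among the called probes well above background on all 4 arrays compared. The labels speak of 2 independent experiments per group, and the p-values measure only the spread between these arrays.

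In leaves the cold samples differed from the controls by a strong rise of Wcor15, a wheat cold-responsive gene whose product is directed to the chloroplast. Wcor15 was not well above background on either array at 24 °C and reached a level of -0.74 ± 0.05 (log2, SD, n = 2) at 4 °C. That is 43.7-fold above the mean of the lowest signals counted as well above background on the control arrays. The fitted change was 7.01 on the log2 scale with a standard error of 0.192 (limma, Benjamini-Hochberg adjusted p = 2.99e-06), number 47 in size among the rises of the 29604 probes tested; it rests on control signals below that limit and is no bound. Alternatives chosen after the data were seen gave 5.30 with signals raised to 1 common floor on all arrays, and 3.12 and 3.88 with a normexp background correction. RD29B, in Arabidopsis the name of a gene induced by drought and abscisic acid, went the other way, from -4.56 ± 0.34 to -6.46 ± 0.02, or 3.74-fold lower (limma, Benjamini-Hochberg adjusted p = 0.000116). With the normexp correction followed by quantile normalization its change was -0.33, short of 2-fold. RD29A, cor47, DREB2A and DREB2B, which bear the names of Arabidopsis genes of the drought and cold response, were not well above background on any array, and the files do not say which species' sequences these probes carry.

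Among probes well above background on all 4 leaf arrays, the largest rise was that of wheat0130Contig15644, which went from -5.46 ± 0.04 to 3.83 ± 0.01, a 626-fold increase (limma, Benjamini-Hochberg adjusted p = 2.1e-07); over the alternatives its log2 change of 9.29 ranged from 7.20 to 9.69. It was already high in crown at 24 °C, at 2.39 ± 0.01. The largest fall among the same probes was that of whsh_allContig1173, from 6.78 ± 0.06 to -4.26 ± 0.10, a 2112-fold decrease with the same adjusted p from limma and Benjamini-Hochberg and a log2 change from -11.12 to -9.23 over the alternatives. Over all probes, 3820 were higher and 6118 lower in the cold by at least 2-fold with a limma Benjamini-Hochberg adjusted p under the threshold of 0.05, together 33.6% of those tested. Of these, 2822 of the higher and 5432 of the lower were well above background in both groups. The folds of the others rest in part on signals not well above background. Among the probes well above background in both groups, 98 rose and 180 fell by at least 16-fold. As the cold leaf arrays had the lower detection limit, falls could be followed further down than rises. Higher probes made up 38.4% of the calls with scaling to the 75th percentile, 52.4% with scaling to the median, 51.8% after quantile normalization, 49.5% after cyclic loess, 61.9% with scaling to spike-in controls and 19.9% with the normexp correction and the 75th percentile. Which direction prevailed in leaves thus depended on the scaling. Cold leaves came from older plants than the controls, and each group was scanned on a day of its own, so that temperature cannot be told apart from either.

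**Figure D1:**
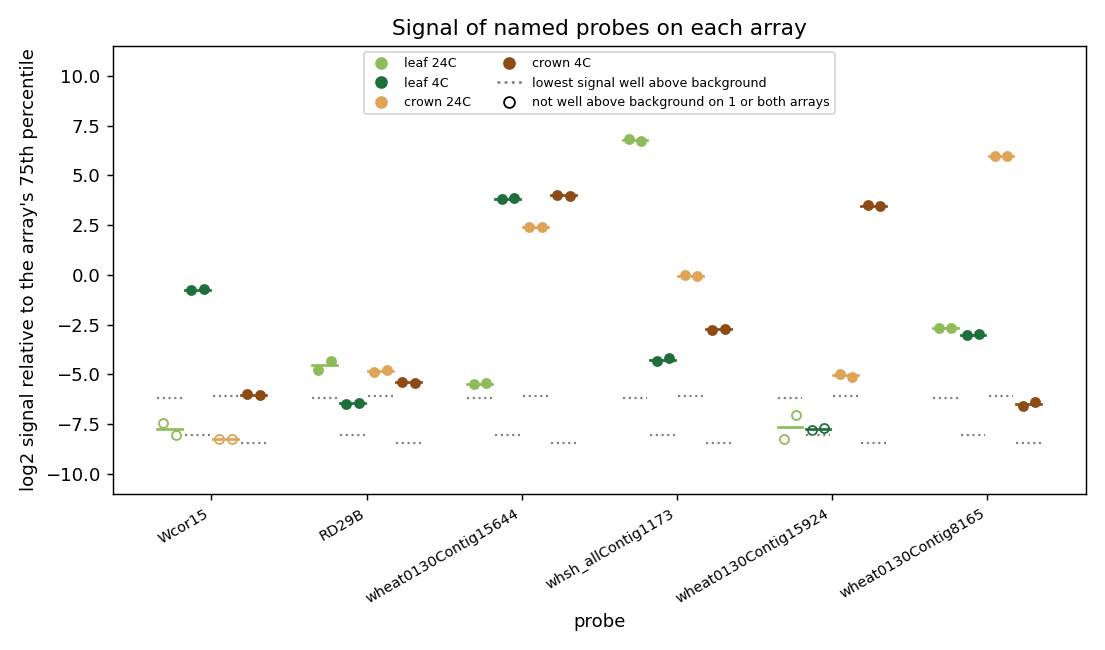
Signal of 6 named probes on each of the 8 arrays, as log2 relative to the array's 75th percentile (vertical axis), with points for the arrays, colours for the 4 groups, short solid lines for group means, dotted lines for the group's mean lowest signal well above background, and open points where a probe was not well above background on 1 or both arrays. Wcor15 stands at -0.74 in cold leaves and at -6.01 in cold crowns, and wheat0130Contig8165 drops from 5.98 to -6.50 in crown only.

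In crowns after 6 weeks in the cold, Wcor15 was well above background on both arrays, at -6.01 ± 0.05, and at 24 °C on neither. This is 1.05-fold the mean lowest signal well above background on the control arrays. The fitted change of 2.23 (standard error 0.192; limma, Benjamini-Hochberg adjusted p = 0.000142) rests on control signals below that limit. With the normexp correction it was -0.42 with the 75th percentile (limma, Benjamini-Hochberg adjusted p = 0.336) and 0.33 with quantile normalization (adjusted p = 0.000615 from the same test), and over 24 alternatives the adjusted p ranged from 3.91e-06 to 0.336. RD29B stood at -4.82 ± 0.08 at 24 °C and -5.41 ± 0.01 at 4 °C, a change of -0.59 that stayed below the 2-fold limit and turned to 0.41 with scaling to the spike-in controls. Among probes well above background on all 4 crown arrays, the largest rise was that of wheat0130Contig15924, from -5.05 ± 0.12 to 3.47 ± 0.03, or 367-fold (limma, Benjamini-Hochberg adjusted p = 9.18e-06; log2 change 8.52, from 6.67 to 9.52 over the alternatives), and on the leaf arrays this probe was not well above background in either group as a whole. The largest fall among them was that of wheat0130Contig8165, from 5.98 ± 0.01 to -6.50 ± 0.12, or 5701-fold (limma, Benjamini-Hochberg adjusted p = 1.14e-07; log2 change -12.48, from -12.61 to -9.46 over the alternatives), while its level in leaves was -2.67 ± 0.03 at 24 °C and -3.01 ± 0.03 at 4 °C.

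Over all probes tested in crown, 6565 were higher and 5131 lower in the cold by the same criteria, 36.3% of 32204. Of these, 4915 of the higher and 4596 of the lower were well above background in both groups, so that 51.7% were higher. The folds of the others rest in part on signals not well above background. Of 3541 probes well above background in crown only at 4 °C, 609 were at least 2-fold higher when measured from the detection limit. With scaling to the 75th percentile, large changes were mostly falls. Among probes well above background in both groups, 495 fell and 64 rose by at least 16-fold. The cold crown arrays had the lower detection limit, so falls could be followed further down than rises. The split was not counted under the other scalings. Of those 495, 231 were also called lower in cold leaves and 44 higher. Crown tissue at 4 °C was likewise older than its control and scanned on another day, so that temperature cannot be told apart from age or scan day. Higher probes made up 56.1% of the calls, but 88.8% with scaling to 7 spike-in controls (18000 higher and 2266 lower) and 38% with the normexp correction and the 75th percentile.

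The leaf and crown responses share no array and can be set side by side. Of 29012 probes tested in both, 1125 were higher in both tissues and 1789 lower in both, against 728 and 922 for independent lists of the same sizes. Opposite calls were fewer than for independent lists: 480 probes were higher in leaf and lower in crown, for 567, and 1017 were lower in leaf and higher in crown, for 1184. The balance within the shared calls depended on the processing: scaling to the spike-in controls gave 4411 higher and 708 lower in both, quantile normalization 1511 and 1570, and the normexp background correction with the 75th percentile 351 and 2019. Both cold groups were read with the same software version and had lower limits of detection than both control groups, a technical difference that runs the same way in both tissues and that the numbers for independent lists do not allow for. Across probes, which are not independent replicates, the changes correlated at a Pearson r of 0.234 and a Spearman rho of 0.201. At the extreme, 13 probes rose and 133 fell by at least 16-fold in both tissues by the fitted values. Of the 13 that rose, 4 were well above background on all 8 arrays. Of those 133, 55 were not above background on any cold array, and with signals on all arrays raised to 1 common floor the number of such falls was 46. It was 31 with only probes well above background on all 8 arrays, and 8 and 14 with normexp followed by quantile normalization and by the 75th percentile. These 133 probes also differed between the 2 crown controls: their median was 1.97-fold higher on the array of replicate 2 than on that of replicate 1, whereas 14108 other probes of like level differed by a median of 0.01 on the log2 scale.

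**Figure D2:**
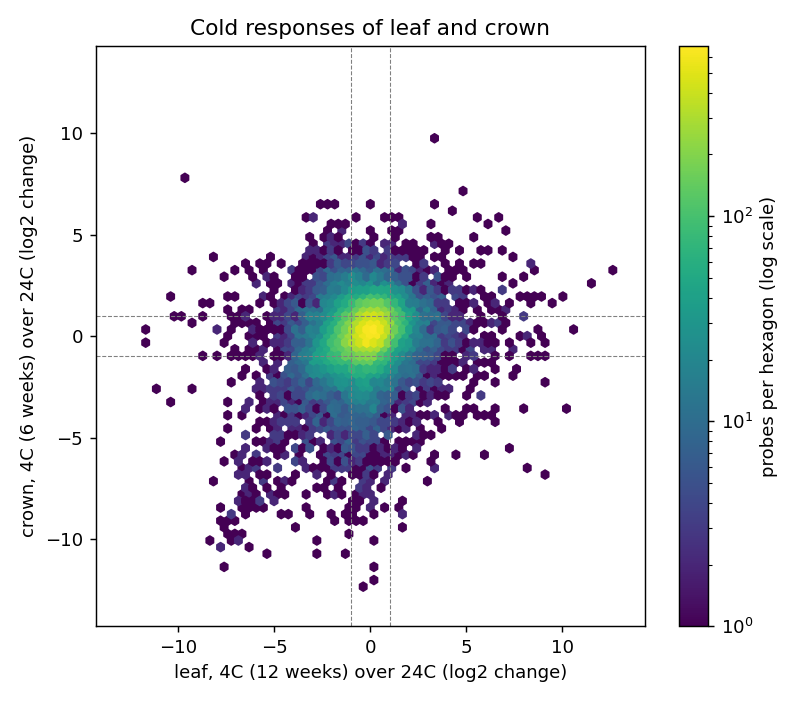
Change in the cold of the 29012 probes tested in both tissues, with the leaf change on the horizontal and the crown change on the vertical axis (both log2, 4 °C over 24 °C), hexagons coloured by the number of probes on a log scale and dashed lines at a 2-fold change. Most probes lie near the centre, r is 0.234, and a group at the lower left fell strongly in both tissues.

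The cold responses themselves were compared between the tissues with the interaction term of the fit. At 4 °C the signal of Wcor15 in leaf was 38.6-fold that in crown, with both values well above background. Its fitted crown response minus leaf response was -4.78 on the log2 scale (standard error 0.271; limma, Benjamini-Hochberg adjusted p = 3.3e-05), which rests on 24 °C signals at background in both tissues and is not a measured difference of changes. RD29B differed by 1.32 in the other direction (limma, Benjamini-Hochberg adjusted p = 0.00258), since its fall was larger in leaf; with normexp and quantile normalization its changes were -0.33 in leaf and -0.05 in crown, and with normexp and the 75th percentile -1.41 and -0.75, so that the tissues then differed by less than 2-fold. Over 32796 probes, the change was higher in crown for 9624 and higher in leaf for 5382. Calls higher in crown made up 64.1% with scaling to the 75th percentile, 50.4% with scaling to the median, 53.3% after quantile normalization, 51.4% with normexp and quantile normalization, and 82.2% with scaling to the spike-in controls. The crown spent 6 weeks and the leaf 12 weeks at 4 °C, so that the tissue and the length of the cold treatment cannot be told apart here. Plant age at 4 °C went with that length. Each group also had a scan day of its own, leaf at 24 °C had a scanner of its own, and the controls differed in software version. The difference cannot be told apart from these either.

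At 24 °C the tissues differed for 54.9% of the probes tested, a larger share than in either cold response. Of the 29689 tested, 8613 were higher in crown and 7685 higher in leaf by at least 2-fold (limma, Benjamini-Hochberg). Those higher in crown were 52.8% of the calls, but 48% with the authors' table, 49% after quantile normalization, 48.9% with only probes well above background on all 8 arrays and 80.4% with scaling to the spike-in controls, so that the prevailing direction depended on the processing. wheat0130Contig15644 was 231-fold higher in crown, wheat0130Contig8165 403-fold higher in crown and whsh_allContig1173 113-fold higher in leaf, each with a limma Benjamini-Hochberg adjusted p of 2.1e-08 or less. These probes were chosen for the largest cold changes, which use the same 24 °C arrays. Their folds and p-values here are therefore not independent of that choice. Wcor15 was at background in both tissues, and RD29B differed by -0.27 with an adjusted p of 0.156 (limma, Benjamini-Hochberg), so no difference of RD29B was detected. The comparison was repeated at 4 °C, after the data were seen and on other arrays. Of the probes higher in crown at 24 °C and tested at both temperatures, 6370 of 8449, or 75.4%, were again called higher in crown, against 2801 for independent lists. Of those higher in leaf, 4695 of 7618, or 61.6%, were again called higher in leaf, against 1883. The tissue differences correlated across probes at r = 0.786 between the temperatures. The leaf controls were scanned on another scanner than all other groups, which limits this comparison as it does the leaf response.

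**Figure D3:**
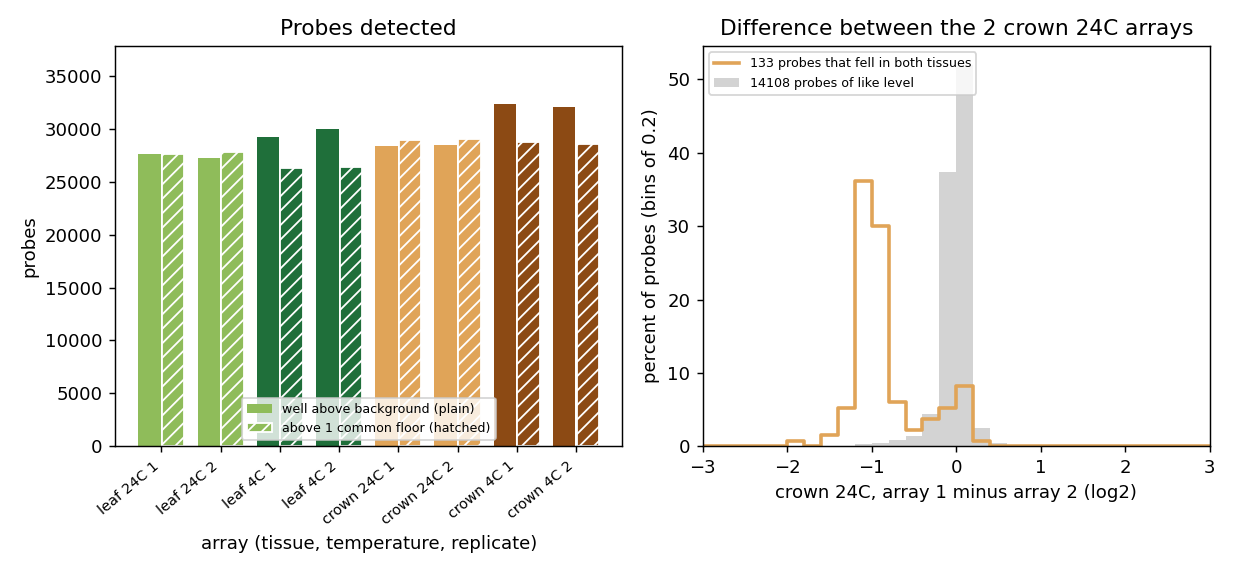
Left: number of the 37826 probes well above background (plain bars) and above a floor common to all arrays (hatched bars) on each array, by group colour. The cold arrays have more probes well above background than the controls of their tissue, but fewer above the common floor. Right: difference between the 2 crown arrays at 24 °C (log2, array 1 minus array 2) for the 133 probes that fell at least 16-fold in both tissues (line) and for 14108 probes of like level (grey bars), in percent of probes per bin; the line peaks near -1 and the bars at 0.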

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

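Each test in this part except the interaction term was chosen after the data were seen; what cyclic loess would show was written down before its own result was seen, though after that of quantile normalization, and for the common floor, spike-ins, scan days and the probes that fell in both tissues only afterwards.

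The leaf and crown responses to cold differed by a test of the difference itself, the interaction term in limma, which gave 9624 probes with a higher change in crown and 5382 with a lower one. Of these, 6296 and 3942 were well above background on all 8 arrays. For Wcor15 the fitted crown change minus leaf change was -4.78 by the same test, but Wcor15 was at background on all 4 arrays at 24 °C, so that value is no measured difference of changes. Tissue and weeks at 4 °C differ together between these groups, so neither can be assigned to the difference. Each group also had a scan day of its own, so the difference cannot be told apart from scan day either. A signal also appeared in spots that no comparison used. The control eQC-40, on 10 spots of each array, had medians of -0.57 and 0.12 in leaf at 24 °C, 7.65 above those in crown at 24 °C on the log2 scale. In crown at 24 °C 1 and 0 of the 10 spots were well above background, so 7.65 is not a measured difference, and the lowest probe signals well above background there were -6.09 and -6.08. It lay at -4.35 and -4.53 on the cold leaf arrays and at -4.94 and -5.04 on the cold crown arrays. What this control stands for is not stated in the files, and no explanation was tested.

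More probes were well above background at 4 °C than at 24 °C, by a mean of 2160 in leaf and 3796 in crown. A lower detection limit on the cold arrays is a candidate explanation: with 1 common floor the difference was -1383 in leaf and -315 in crown. With scaling to the median of 7 spike-ins the difference was -364 in leaf and 1503 in crown, so that in crown the scalings give opposite signs. In leaf both go against a larger number of expressed transcripts, but scaling to single spike-ins gave from -1892 to 1138 in leaf, so it stays open there as well as in crown, where the range was 960 to 1760. Plant age was not tested.

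Of the probes tested, 33.6% were called in leaf and 36.3% in crown. A smooth intensity-dependent response of scanner or hybridisation as the whole cause is argued against by cyclic loess. After it, 89.1% of the leaf calls and 90% of the crown calls stayed in the same direction. Cyclic loess starts from the same background-subtracted signal, so it cannot test differences that arise from the background. With normexp and quantile normalization, 5507 of 9938 leaf calls and 6980 of 11696 crown calls stayed. With normexp and the 75th percentile, 7753 and 7786 stayed. A scan day, slide and hybridisation of its own for each group cannot be told apart from the temperature, because the largest number of scan days of a group is 1. The cold treatment and plant age stay among the open explanations, as untested.

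The 133 probes that fell at least 16-fold in both tissues had a median of -0.976 for array 1 minus array 2 of crown at 24 °C, with 121 of the 133 lower on array 1, against a median of 0.01 for probes of like level. In leaf at 24 °C the median was -0.25, against -0.01. RNA of a single source besides the bulk of the tissue, present in the 24 °C samples, is a candidate explanation, as such a source would move its members together between arrays of 1 group. Plant transcripts regulated as 1 group could do the same, as the labels speak of 2 independent experiments per group. The shift between the arrays therefore does not separate these explanations. Plant transcripts regulated as 1 group stay open: 76.7% of the members lay within 2-fold of their median crown over leaf difference, against 55.3% of the other probes lower in both tissues, which either explanation gives. The files do not name the genes, so the source was not identified.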

How the results depend on the processing

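The tests in this part that were chosen after the data were seen are normexp on median signals, the slide block, the filter on all arrays compared, the common floor, the spike-in scaling and cyclic loess. Of the counts compared over 27 alternatives, 257 stayed within 1.5 times their value in the report and 38 moved further. Of the other values, 276 kept their direction and side of the threshold, whatever their size (r within 0.05, the count of 16-fold falls within 1.5 times), 7 moved, 2 reversed, 1 passed and 2 fell short of the threshold. The cause was not tested except where the construction shows it.

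Without a filter on dim probes, which adds probes at background, 12225 were lower in leaf, 9408 lower in crown and 5775 lower in both. With only probes above background on all 8 arrays, which tests fewer, 4199 were higher in crown, 6334 higher in the difference and 657 higher in both. With the filter on the arrays compared the last 2 were 6301 and 657. Without a fold threshold, which admits small changes, 10383 were higher and 12462 lower in leaf, 13970 and 10307 in crown, 14714 and 9538 in the difference, and 13227 and 12268 between tissues at 24 °C. The overlap was then 5554 higher in both, 5171 lower in both and 7173 opposite.

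With normexp and quantile normalization, 3089 were lower in leaf, 3664 higher in crown and 4826 higher in the difference, with 516 higher in both, 907 lower in both and 728 opposite. With normexp and the 75th percentile, 1977 were higher in leaf, 3148 higher in crown, 351 higher in both and 958 opposite, and Wcor15 in crown turned to -0.42. With the spike-in scaling, 6798 were higher in leaf, 18000 higher and 2266 lower in crown, 15262 and 3313 in the difference, 16167 and 3952 between tissues, 4411 higher in both and 708 lower in both, and RD29B in crown turned to 0.41. That scaling moved the median change of all probes tested from -0.09 to 0.30 in leaf, from 0.17 to 1.16 in crown, from 0.32 to 0.92 in the difference and from 0.08 to 1.19 between tissues.

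Wcor15 in leaf ranged from 3.12 to 7.66 over 25 alternatives and its difference between tissues from -5.31 to -3.54 over 24, past the threshold in each; the filters on all arrays give it no value. The 4 probes named by contig stayed past it over 26 or 27. They had been chosen for the largest changes in the same data, so staying past a 2-fold limit says little.

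With replicate number as a block, 3811 were higher and 6107 lower in leaf, 6549 and 5118 in crown, 9570 and 5363 in the difference, and 8603 and 7679 between tissues.

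Leaving out each array in turn, with the lone array assumed to vary like the other groups, gave 3777 to 3913 higher and 6051 to 6440 lower in leaf, 6176 to 6595 and 4917 to 5316 in crown, 8995 to 9859 and 5230 to 5535 in the difference, and 8391 to 8912 and 7632 to 7844 between tissues. The overlap ranged from 1085 to 1166 higher in both, 1693 to 1835 lower in both and 1430 to 1573 opposite. The 133 probes that fell 16-fold in both ranged from 125 to 143, but were 46 with the common floor, 31 with either filter on all arrays, and 8 and 14 with normexp.

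Signal over background limits folds of probes at background. The planned normexp on mean spot signals and all alternatives for gene lists were not run, for want of that column and of annotation.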

Other observations

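The tests and counts in this part were all chosen after the data were seen.

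Of the 116 probes with names beginning whdp that were well above background in both tissues at 24 °C, 31, or 26.7%, fell at least 16-fold in both, against 0.409% of the probes with other names. These 31 belong to the 133 probes whose median differed 1.97-fold between the crown arrays at 24 °C and whose number was 46 with the common floor, 31 with only probes well above background on all 8 arrays, and 8 and 14 with normexp; the share was not computed under these alternatives. The meaning of the name is not stated in the files. Such shares were computed for the 26 families of probe names with a member among the 133, and whdp was singled out from these. The family whe had 10 of 307, or 3.26%, and the family wheat 24 of 10435, or 0.23%.

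Among 41 families of probe names, camera with a preset correlation of 0.01 passed 2 in the leaf response, 1 in the crown response and 12 between the tissues at 24 °C, and with an estimated correlation 0 in each. The whsh_all probes had a median change of -0.61 in cold leaves over 902 probes (camera, Benjamini-Hochberg adjusted p = 0.0048), and -0.22 with the spike-in scaling. Between the tissues at 24 °C their median was -2.09 over 904 probes (adjusted p = 1.53e-10), with 110 higher in crown and 535 higher in leaf, and -0.97 with the spike-in scaling. With an estimated correlation the adjusted p was 0.977 and 0.178. The whdp probes had a median of -0.86 in cold leaves (camera, adjusted p = 0.0329 with the preset and 0.977 with the estimated correlation), and -0.47 with the spike-in scaling. In cold crowns their median was -0.81 (camera, adjusted p = 0.000762 with the preset and 0.981 with the estimated correlation), and 0.19 with the spike-in scaling. That scaling shifts all probes of an array alike, and the median of all probes tested in crown moved from 0.17 to 1.16. It can therefore change the sign of a family median, but not its distance from the other probes.

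Of the 24596 probes well above background on all 8 arrays, 105 were at least 16-fold higher in crown at 24 °C than in each other group, against 20 for leaf at 24 °C, 15 for leaf at 4 °C and 10 for crown at 4 °C. Lower than in each other group were 21 in crown at 24 °C, 24 in leaf at 24 °C, 21 in leaf at 4 °C and 47 in crown at 4 °C.

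For 921 pairs of probes with names that differ by a leading r, the changes correlated across pairs at 0.557 in leaf and 0.578 in crown. The change of the r probe minus that of the plain probe was 0.34 ± 0.03 in leaf (mean, SE over pairs, with mean changes of -0.09 and -0.44) and -0.45 ± 0.04 in crown (-0.22 and 0.23). The SEs here and below run over pairs, which are not independent replicates. They do not measure the spread between arrays. A loess trend of change on mean signal was then fitted to contig probes in each tissue and subtracted. The r minus plain difference was then 0.13 ± 0.04 in leaf and -0.50 ± 0.04 in crown. Without that step it was 0.56 ± 0.15 in leaf and -0.02 ± 0.13 in crown in the 122 pairs with the plain probe brighter. In the 799 pairs with the r probe brighter it was 0.31 in leaf and -0.51 in crown, so it differed with which probe was brighter. Of the pairs called on both probes, 12 of 149 in leaf and 9 of 114 in crown went in opposite directions.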
